A study of Mus musculus with 3 samples.

How the data were processed

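RNA from 3 primary cultures of mouse ocular pigment epithelium was measured on 1 biotin-labelled array each: iris (IPE), ciliary body (CBPE) and retinal (RPE) pigment epithelium. Per the labels' protocols, the donors were C57BL/6 mice of 6 to 8 weeks. IPE and CBPE were grown in RPMI 1640 with 10% serum and RPE in DMEM with 20% serum, and every culture spent the night before RNA extraction in medium without serum. Per the labels' protocols, 1 µg of total RNA was reverse transcribed from an oligo-dT primer carrying a T7 promoter, and the labelled RNA was made with Affymetrix in vitro transcription reagents. The sample descriptions give the share of cytokeratin-positive cells as above 99% for IPE and above 95% for CBPE and RPE, and a culture time of 14 days for CBPE and RPE only.

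The deposited table holds linear intensity values, 1 per probe set and array, for 45101 probe sets, of which 64 are control probe sets. The software and the summary method are not given in the sources used here. The 2% trimmed mean of the deposited intensity values was 100.001 on every array, so the arrays had been scaled to a common target, and the values were kept on that scale. Spot-level values and detection calls were not used here. Array depth has no counting unit, and the single array per culture limits the precision of every value.

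Gene symbols came from an annotation table of the array platform from 2016, updated through the gene identifier to the RefSeq gene table of assembly GRCm38.p6. Of 35890 listed probe sets, 34958 had 1 gene and 932 had several, and the latter were not used for names. A further 9160 probe sets were not listed and stayed unnamed here. No coordinates of genes or probe sets are given here.

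A floor was set on each array at the 50th percentile of its non-control probe sets, which was 14.5 for IPE, 17.3 for CBPE and 16.8 for RPE. Signals under the floor were set to it before log2 was taken, so differences between values at the floor have no meaning. The 27 probe sets for bacterial transcripts absent from the samples reached 7.9, 20.2 and 16.6 on these arrays. A gene was represented by its probe set with the highest mean log2 signal over the 3 arrays, giving 18193 genes, of which 13345 were above the floor on at least 1 array. A gene was counted as different between 2 arrays when its signals differed at least 2-fold and at least 1 of them was above the floor. Where 1 array was at the floor, the fold is the bright signal over the floor of the other array and is written as at least that size. Where the dim signal was in CBPE and under the 20.2 of the absent bacterial controls, the printed fold is over 20.2 instead. The counts and log2 differences kept the floor.

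With 1 array per culture no test between cultures can be made, and no p-value, standard error or count of significant genes is given. The only error that could be measured was the disagreement between probe sets of the same gene with signals above 100 on both arrays. Its pooled SD of the log2 difference was 0.45 for RPE against IPE over 1773 genes, 0.29 for RPE against CBPE over 1693 genes and 0.49 for CBPE against IPE over 1666 genes. It leaves out the spread between cultures, animals and hybridisations. Correlations are across genes, which are not independent replicates.

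For 33 gene lists, 9 of them markers of other cell types, the median log2 difference of the members above the floor on at least 1 of the 2 arrays was computed where 5 or more were measured, which was the case for 32 lists in each of the 3 comparisons. Each median was placed among the medians of 10000 random gene lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart below percentile 2.5 or above percentile 97.5. With 96 medians, 4.8 would do so if lists were random sets of genes. The percentile describes these 2 arrays and is not a test of the tissues. Every list, the counting rules and the rule for naming genes were fixed before the data were examined.

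The named genes are, per comparison, the 8 with the largest difference in each direction among genes above the floor on both arrays whose probe sets agreed in direction, the 4 brightest in each direction that were at the floor on the other array, up to 4 members per list with at least a 2-fold difference taken by mean expression, and the 8 genes Thbs1, Tgfb1, Tgfb2, Tgfb3, Cd36, Cd47, Cd80 and Cd86. For genes that set a culture apart from both others, the 6 with the largest smaller difference are named in each direction, among genes above the floor on all 3 arrays whose probe sets agreed in direction. Transcripts known only by a clone or predicted-gene name are counted but not named. The closing section also names genes from 5 further lists written after the first results were seen. Of 100 lists drawn at random from all simulated genes, whose noise was independent between genes, 93, 93 and 92 lay inside the central 95% in the 3 comparisons.

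The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data with noise set below the observed spread between the arrays. Dim genes were not covered, since the 200 genes changed 4-fold were drawn only from those well above the floor. Of these, 99.5% were recovered for RPE against IPE, 100.0% for RPE against CBPE and 98.5% for CBPE against IPE, with 86, 0 and 109 unchanged genes passing the 2-fold limit at an assumed noise (an SD per array of 0.267, 0.168 and 0.281 on the log2 scale). The alternatives were floors at the 25th and 60th percentile, a pseudocount in place of the floor, quantile normalization, equal medians, the mean of all probe sets of a gene, and leaving out probe sets that can match several transcripts. A fixed floor of 100 was added after the data were seen.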

Results

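The series compared gene expression in 3 kinds of primary cultured mouse ocular pigment epithelium: the pigmented layer of the iris (IPE), of the ciliary body, which secretes aqueous humour (CBPE), and of the retina, which serves the photoreceptors (RPE). Its title asks about thrombospondin-1 and the T cell response to these cells. Each culture was hybridised to 1 array, so no replicates exist and every value below is a single measurement without a replicate error. IPE had 11473 genes above the floor, CBPE 11921 and RPE 11642, and 10244 genes were above it on all 3 arrays. Each floor was the median of that array's own non-control probe sets, so the share of probe sets above it was set beforehand. The counts per array therefore do not show how many genes a culture expressed. RPE was grown in another medium with more serum (20% against 10%), so medium and tissue cannot be told apart in either comparison with RPE.

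The control probe sets differed between the arrays. The ratio of 3′ to 5′ signal of the Actb controls was 2.26 in CBPE and 2.25 in RPE, against a 3′ signal of 3976 over a 5′ signal of 2646 in IPE. That of the Gapdh controls was 0.940 in IPE, 1.23 in CBPE and 1.25 in RPE. The 5′ probe set of 18S ribosomal RNA gave a signal of 274.3 in CBPE against 17.6 in IPE and 27.7 in RPE. The 12 probe sets of the hybridisation controls bioC, bioD and cre, which are added in fixed amounts, had a geometric mean signal of 1239 in IPE, 3192 in CBPE and 1941 in RPE after the common scaling, a ratio of 2.58 between CBPE and IPE. Those of the control bioB were left out, and reached at most 5 in IPE, 17.4 in CBPE and 2.1 in RPE, near or under the floors. The brightest signal was 8441 in IPE, 19334 in CBPE and 13849 in RPE, while the 75th percentile was highest in IPE, at 100.2 against 76.4 and 82.9. The range of bright signals was thus narrowest on the IPE array.

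RPE and CBPE were the closest pair. Across genes, the Pearson correlation of log2 signals was 0.958 for RPE and CBPE (Spearman 0.941, 12860 genes), 0.901 for RPE and IPE (Spearman 0.895, 12446 genes) and 0.883 for CBPE and IPE (Spearman 0.874, 12831 genes). At least 2-fold differences were found for 8.01% of the genes between RPE and CBPE, 20.3% between RPE and IPE and 24.3% between CBPE and IPE. IPE was at least 2-fold above both other cultures for 853 genes and below both for 815, against 291 and 292 genes for CBPE and 102 and 137 for RPE. The even split for IPE depended on the scaling, with 449 above and 1424 below with equal medians, and 627 and 958 after quantile normalization. Both comparisons with IPE share its single array, so whatever is particular to that array enters both.

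Thbs1, which encodes thrombospondin-1, a secreted matrix protein that can activate latent TGF-β, was among the bright genes of all 3 cultures, and its 2 probe sets ranked the cultures differently. The brighter probe set, which represents the gene here, gave a signal of 2992 in IPE, 6419 in CBPE and 3832 in RPE, whereas the other gave 3146, 2739 and 1591. By the brighter probe set CBPE was 2.15-fold above IPE, and by the other IPE was 1.15-fold above CBPE. Both probe sets placed CBPE above RPE, by 1.67-fold and 1.72-fold. After quantile normalization the log2 difference between CBPE and IPE by the brighter probe set was 0.26, which is within the SD of 0.49 between probe sets of a gene, and RPE minus IPE turned from 0.36 to -0.19. The related gene Thbs2 was 2.10-fold higher in CBPE and 2.19-fold higher in RPE than in IPE. Of the thrombospondin receptors, Cd47 was at 855.3 in IPE, 1692 in CBPE and 1220 in RPE by its brightest probe set, while another placed IPE above RPE at 802.1 against 687.1. Cd36, a scavenger receptor, was above the floor in CBPE alone, at a signal of 43.1.

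**Figure D1:**
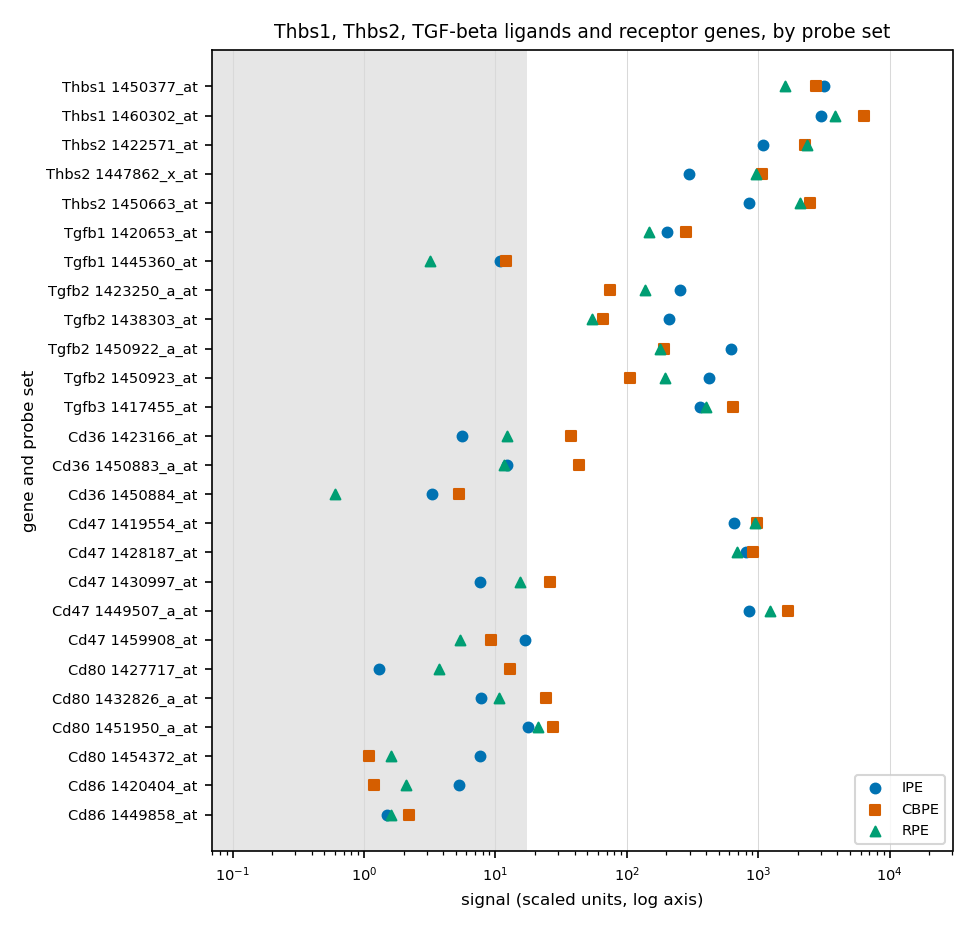
Signals of each probe set (rows) of Thbs1, Thbs2, the TGF-β ligands, Cd36, Cd47, Cd80 and Cd86 on a log axis of scaled signal units, with 1 point per array for IPE, CBPE and RPE and no error bars because there are no replicates. The shaded range ends at the highest of the 3 floors, 17.3, and the 2 Thbs1 probe sets at the top place IPE differently relative to CBPE.

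The TGF-β ligands divided by gene. Tgfb2 was higher in IPE than in both other cultures, at a signal of 622.6 against 192.4 in CBPE and 179.1 in RPE, which is 3.24-fold and 3.48-fold, and its 4 probe sets all had IPE highest. Tgfb3 was brightest in CBPE at 637.1, against 357 in IPE and 402 in RPE, which is 1.78-fold and 1.58-fold and below the 2-fold limit. Tgfb1 was at 201 in IPE, 282.7 in CBPE and 147 in RPE, differences below 2-fold. None of the 20 measured TGF-β family receptors and SMADs was at least 2-fold higher in CBPE or RPE than in IPE, while 5 were at least 2-fold lower in each. The receptor gene Tgfbr1 was 3.29-fold higher in IPE than in CBPE and 2.59-fold higher than in RPE, and Bambi, which encodes a pseudoreceptor that dampens TGF-β signalling, 3.88-fold and 5.94-fold. The median log2 difference of that list was -0.44 in CBPE minus IPE (percentile 1.97 among random lists) and -0.50 in RPE minus IPE (percentile 0.69). Glial markers, at percentiles 0.13 and 0.02, and the Actb and Gapdh 3′ to 5′ ratios set IPE apart in the same comparisons. Of 23 measured TGF-β response genes, 9 were at least 2-fold higher and 2 lower in CBPE than in IPE, with Lox 2.70-fold and Ccn1 4.04-fold higher and a median of 0.77 (percentile 99.3), which lay at percentile 90.6 after quantile normalization. In RPE minus CBPE the same list had a median of -0.55, below all 10000 random lists, with Tgfbi 2.13-fold, Itga5 2.80-fold lower in RPE and Bhlhe40 at 137.5 in RPE against 549.9 in CBPE. The list shares Acta2 and Tagln with the smooth muscle markers and Col1a1, Fn1 and Postn with the fibroblast markers, which moved with it, at percentiles 96.1 and 98.7 in CBPE minus IPE and 0.34 and 1.59 in RPE minus CBPE. It did not stand apart in RPE minus IPE (percentile 36.6), nor did the receptors and SMADs in RPE minus CBPE (percentile 5.10). Of the latent-complex genes, Ltbp2 was 8.43-fold higher in CBPE and 5.65-fold higher in RPE than in IPE.

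The lists of melanin genes and regional eye transcription factors were higher in IPE than in both other cultures. Of 14 measured melanin and melanosome genes, 12 were at least 2-fold lower in CBPE than in IPE and none higher, and of 13 measured, 11 were lower in RPE than in IPE and none higher. The tyrosinase gene Tyr was 2.90-fold and 2.26-fold higher in IPE than in CBPE and RPE, Tyrp1 was 20.7-fold and 2.52-fold higher, and Dct, which like Tyrp1 acts in eumelanin synthesis, was at least 70.7-fold and 4.99-fold higher. The list medians were -2.33 in CBPE minus IPE and -1.55 in RPE minus IPE, below all 10000 random lists in both. RPE lay between the others: 5 of 13 measured members were at least 2-fold higher in RPE than in CBPE, none lower, and the median was 0.69, above all 10000 random lists. Of the 21 measured regional eye transcription factors, 12 were at least 2-fold higher in IPE than in CBPE and 12 than in RPE, while 2 were lower in IPE than in CBPE and 1 than in RPE, with Foxc2 at 17.8 in IPE against 342.3 and 176.6. Pax6, a master regulator of eye development, was at 897.7 in IPE, 177.1 in RPE and 19.4 in CBPE, the last under the 20.2 that absent bacterial controls reached on that array. Nr2f1 was 13.3-fold and 10.4-fold higher in IPE than in CBPE and RPE, and Zic1 at least 14.1-fold and at least 17.0-fold higher. The medians of this list were -1.59 in CBPE minus IPE and -1.64 in RPE minus IPE, and it lay at percentile 67.6 in RPE minus CBPE. Both lists stood apart in both comparisons with IPE under every alternative. By their medians, glial markers moved the same way as the melanin genes, at percentiles 0.02 in RPE minus IPE, 0.13 in CBPE minus IPE and 100 in RPE minus CBPE. Apoe, Glul and Dkk3 were highest in IPE, but Fabp7 was highest in CBPE, at 35.6, and Slc1a3 in RPE, at 47.2.

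**Figure D2:**
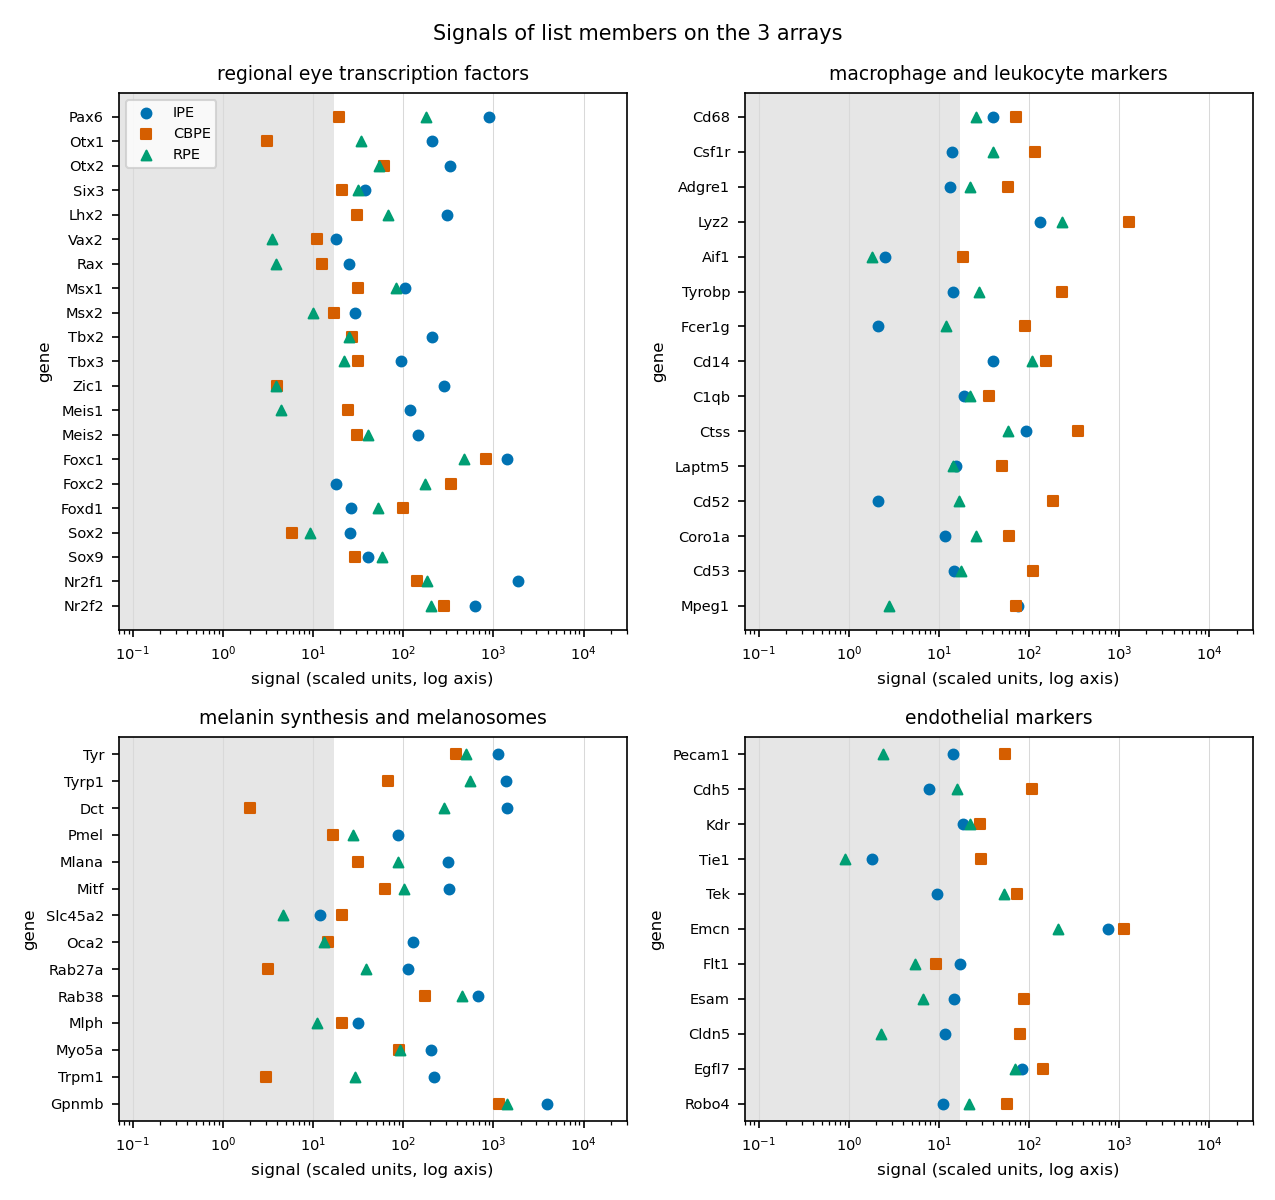
Signals of the members of 4 gene lists on a log axis of scaled signal units, 1 point per gene and array for IPE (circles), CBPE (squares) and RPE (triangles), with values up to the highest floor shaded. IPE points lie to the right for most melanin genes and eye transcription factors, such as Pax6 at 897.7, and CBPE points lie to the right for most leukocyte and endothelial markers, such as Lyz2 at 1288.

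In RPE against IPE, 1227 genes were at least 2-fold higher and 1303 lower. Among the genes above the floor on both arrays, Sfrp2, a secreted modulator of Wnt signalling, was 326-fold higher in RPE, the collagen gene Col14a1 92.5-fold, the small leucine-rich proteoglycan genes Aspn and Fmod 59.6-fold and 28.2-fold, and the microfibril gene Mfap5 36.3-fold. The IPE signals of Sfrp2, Col14a1 and Aspn, at 17.1, 20.4 and 15, were close to the floor of 14.5, so these folds are imprecise. Myh2, a skeletal muscle myosin heavy chain, was 24.7-fold higher, the angiotensin receptor gene Agtr2 24.3-fold and Gask1b 22.6-fold. Tnmd, a marker of tendon cells, was at least 136-fold and Rgs5, a marker of pericytes, at least 97.6-fold higher in RPE than in IPE. Toward IPE, the aldehyde oxidase gene Aox3 was 49.5-fold higher, the methyltransferase gene Inmt 36.7-fold, the monooxygenase gene Fmo2 31.8-fold, and Dio2, which activates thyroid hormone, 21.3-fold. Aox3 and Fmo2 were at 20.2 and 18.2 in RPE, close to its floor of 16.8, so their folds are imprecise too. Arhgap20, Afap1l2 and Msc were 17.6-fold, 15.5-fold and 15.3-fold higher in IPE, and Vegfa, the vascular endothelial growth factor gene, was at 720.4 in IPE against 55.4 in RPE. Sema3g was at least 20.9-fold, Tnfrsf19 at least 18.2-fold and the leptin receptor gene Lepr at least 11.2-fold higher in IPE.

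Cell cycle genes were higher in both RPE and CBPE than in IPE. Of 27 measured, 14 were at least 2-fold higher in RPE than in IPE and none lower, with a median of 1.05, and of 26 measured, 15 were higher in CBPE than in IPE and none lower, with a median of 1.26. Both medians were above all 10000 random lists, and Cdk1 was 3.24-fold and 4.69-fold higher in RPE and CBPE than in IPE. Between RPE and CBPE, 26 of the 27 measured were within 2-fold (percentile 4.22). Fibroblast and mesenchymal markers were higher in the same 2 comparisons with IPE (percentiles 98.4 and 98.7), as was a skeletal muscle list written later (percentiles 100 and 99.99), and the Actb and Gapdh 3′ to 5′ ratios were lowest in IPE. The amino acid and endoplasmic reticulum stress genes had 10 of 22 measured at least 2-fold higher in CBPE than in IPE, with a median of 0.77 (percentile 99.9), and 9 higher and 1 lower in RPE than in IPE, with a median of 0.45 (percentile 94.4). In RPE minus CBPE that median was -0.25 (percentile 1.28, and 2.63 with the fixed floor of 100). Asns, the asparagine synthetase gene, was 5.75-fold and 5.02-fold higher in CBPE and RPE. Oxidative stress genes lay lower in CBPE than in IPE, with 7 of 14 measured at least 2-fold lower, 2 higher and a median below all 10000 random lists, and in RPE minus IPE the median was -0.50 (percentile 0.11). In RPE minus CBPE it was 0.42 (percentile 99.99), which lay at percentile 93.5 without probe sets that can match several transcripts and 96.2 with the mean of all probe sets. The thioredoxin reductase gene Txnrd1 was 2.56-fold and 3.22-fold higher in IPE than in CBPE and RPE.

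In CBPE against IPE, 1507 genes were at least 2-fold higher and 1609 lower. Sfrp2 was 213-fold, Col14a1 146-fold, the elastin gene Eln 62.7-fold, the matrix metalloproteinase gene Mmp3 45.9-fold and the syndecan gene Sdc4 43.2-fold higher in CBPE, and Chil1, Rarres1 and Crip1 were 49.4-fold, 45.0-fold and 44.8-fold higher. The folds of Sfrp2, Col14a1 and Rarres1 rest on IPE signals of 17.1, 20.4 and 21.4, close to the floor of 14.5. Tnmd and Rgs5 were at least 288-fold and at least 274-fold, and Ctla2a, a cysteine protease inhibitor gene, at least 110-fold higher, while Hnrnpl was at least 40.8-fold higher. The Hnrnpl fold rests on 1 probe set, at 13.3 in IPE, 591.7 in CBPE and 508 in RPE, and no other above the floor could check it. Toward IPE, Spon1 was 79.6-fold, Dio2 44.7-fold, Aox3 36.4-fold, the prostaglandin D2 synthase gene Ptgds 33.5-fold and Inmt 27.3-fold higher, and Pax6 at least 44.4-fold. Cxadr, a receptor of junctions, and Heph, a ferroxidase gene, were 21.1-fold and 20.9-fold higher in IPE, and Fmo2 and Nebl at least 28.6-fold and at least 13.7-fold. Fibroblast and mesenchymal markers had 9 of 25 measured at least 2-fold higher and 2 lower in CBPE than in IPE, with a median of 0.83 (percentile 98.7), and 8 higher and 4 lower in RPE than in IPE, with a median of 0.70 (percentile 98.4). After quantile normalization these lay at percentiles 71.7 and 75.7, with the fixed floor of 100 at 95.8 and 96.3, and the former at 96.1 with the floor at the 60th percentile. In RPE minus CBPE the list lay at 1.59 as deposited and 43.9 after quantile normalization, where its median turned from -0.28 to 0.0087, and it did not stand apart under 3 further alternatives. S100a4 was 14.3-fold higher in CBPE and 11.7-fold higher in RPE than in IPE. Col1a1 was 2.51-fold higher in CBPE than in IPE, and Col3a1, 2.18-fold higher there, had a log2 difference of -0.012 after quantile normalization.

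In RPE against CBPE, 482 genes were at least 2-fold higher and 548 lower. Spon1 was 20.1-fold, Ptgds 13.4-fold, the folate receptor gene Folr1 9.46-fold, Tyrp1 8.18-fold and the urea transporter gene Slc14a1 8.05-fold higher in RPE. Pax6 and Mylpf, a skeletal muscle myosin light chain gene, were at least 8.77-fold and at least 10.3-fold higher. Myl1, another such gene, was 9.33-fold higher, and Tnnc2, a skeletal muscle troponin gene, at least 4.45-fold. Pcp4 was at least 30.0-fold, Dct at least 14.2-fold and Crabp1, a retinoic acid binding protein gene, at least 6.54-fold higher in RPE. Toward CBPE, Ctla2a was 69.1-fold higher and its paralog Ctla2b at least 7.16-fold, a pair whose probes may share transcripts. Agbl5 was 14.0-fold, the interferon-inducible gene Ifi27l2a 10.6-fold, the tachykinin gene Tac1 8.41-fold and Chil1 7.98-fold higher in CBPE. Ctla2a, Agbl5 and Tac1 were at 23.1, 21.9 and 20.9 in RPE, close to its floor of 16.8. Hypoxia and glycolysis genes were lower in RPE than in both others: 9 of 21 measured were at least 2-fold lower than in CBPE and 9 than in IPE, none higher, with medians of -0.98 and -0.90, below all 10000 random lists. Bnip3 was 3.52-fold and Ldha 2.48-fold lower in RPE than in CBPE, and the glucose transporter gene Slc2a1 was 2.19-fold lower in RPE than in IPE. Of 14 measured immediate early genes, 6 were at least 2-fold lower in RPE than in CBPE and none higher, with a median of -0.79, below all 10000 random lists. Leukocyte and endothelial markers were lower in RPE than in CBPE too, with medians of -1.56 and -1.54, and the 5′ signal of the 18S control was 27.7 against 274.3. The immediate early list lay at percentile 9.28 in RPE minus IPE and 94.2 in CBPE minus IPE, where hypoxia and glycolysis genes lay at 91.0.

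By list median, markers of leukocytes and endothelial cells were highest in CBPE. Of 15 measured macrophage and leukocyte markers, 11 were at least 2-fold higher in CBPE than in IPE and 12 than in RPE, none lower. Lyz2, a macrophage lysozyme gene, was 9.84-fold and 5.56-fold higher, Tyrobp at least 15.9-fold and 8.33-fold, and Ctss 3.76-fold and 5.94-fold. The median was above all 10000 random lists in CBPE minus IPE, and at -1.56 below all of them in RPE minus CBPE. Of 11 and 10 measured endothelial markers, 7 were at least 2-fold higher in CBPE than in IPE and 7 than in RPE, none lower, with medians of 1.91 and, in RPE minus CBPE, -1.54, though fewer than 5 were left with the fixed floor of 100. Cdh5, the vascular cadherin gene, was at least 7.47-fold and at least 6.45-fold higher. Some members were not confined to CBPE. The endothelial marker Emcn was at 745.1 in IPE, 1114.8 in CBPE and 211.2 in RPE. The leukocyte marker Mpeg1 was at 75.5 in IPE, 72.1 in CBPE and 2.8 in RPE. In CBPE, 15 leukocyte and 10 endothelial markers were above the floor, against 8 and 5 in IPE and 10 and 5 in RPE. A marker at the floor in IPE or RPE could not come out lower in CBPE, so the absence of lower markers says little. The 18S ribosomal RNA control moved with these lists, at 274.3 in CBPE against 17.6 and 27.7. These markers differed in the same comparisons as every list given here as higher in CBPE. Between RPE and IPE, the medians were 0.44 for leukocyte markers (percentile 95.7) and 0.19 for endothelial markers (percentile 63.7). The leukocyte median turned to -0.086 with the floor at the 60th percentile, and the endothelial median to -0.27 with the floor at the 25th.

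Among genes that bear on T cells, Ctla2a was at least 110-fold and Cd200, an inhibitory ligand gene, 19.6-fold higher in CBPE than in IPE, and leukocyte markers such as Lyz2, at 1288 against 130.9, were higher there too. Cd80 was near the floor, with signals of 17.7 in IPE, 27.6 in CBPE and 21 in RPE, and both probe sets of Cd86 were at the floor in all 3 cultures, so no difference in these co-stimulatory ligands was detectable. Cd200 was 2.13-fold higher in CBPE than in RPE. Vcam1 was 2.47-fold and 3.39-fold higher in CBPE and RPE than in IPE, Fas 2.76-fold and 3.53-fold, and Lgals9, the galectin-9 gene, was 2.21-fold and 2.25-fold higher in IPE. The list of co-stimulatory and co-inhibitory ligands did not stand apart as deposited (percentiles 84.5, 4.57 and 91.0 in RPE minus IPE, RPE minus CBPE and CBPE minus IPE), but lay at percentile 99.92 in RPE minus IPE with the floor at the 25th percentile. The soluble immunosuppressive factors had a median of -0.56 in RPE minus CBPE (percentile 0.01, against 14.0 in RPE minus IPE and 92.2 in CBPE minus IPE), with 4 of 17 measured at least 2-fold lower and 1 higher in RPE. Ctla2a was 69.1-fold lower, and the prostaglandin E synthase gene Ptges was 2.36-fold lower in RPE. Serpinf1, which encodes the pigment epithelium-derived factor, was 3.69-fold and 3.25-fold higher in CBPE and RPE than in IPE, and Lgals1, the galectin-1 gene, 3.13-fold and 2.49-fold.

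Cytokine and chemokine genes were higher in CBPE and RPE than in IPE. Of 26 measured, 11 were at least 2-fold higher and 4 lower in CBPE, with a median of 0.79 (percentile 99.95), and of 24 measured, 8 were higher and 4 lower in RPE, with a median of 0.61 (percentile 99.9), which lay at percentile 84.9 after quantile normalization. In RPE minus CBPE the list lay at percentile 7.14. Leukocyte markers, in CBPE minus IPE, and fibroblast and mesenchymal markers, at percentiles 98.7 and 98.4 in CBPE and RPE minus IPE, were higher in the same comparisons. The monocyte chemoattractant genes Ccl2 and Ccl7 were 3.08-fold and 13.3-fold higher in CBPE and 2.54-fold and 12.9-fold higher in RPE than in IPE, whereas Il6 was 2.26-fold and 4.49-fold higher in IPE. Of the MHC class I genes, H2-K1 was 2.96-fold higher in CBPE than in IPE and 3.13-fold higher than in RPE, although probes for this family can match related genes. B2m was 2.17-fold higher in CBPE than in IPE as deposited, and its log2 difference was -0.11 after quantile normalization. In the order RPE minus IPE, RPE minus CBPE and CBPE minus IPE, the MHC class I list lay at percentiles 77.2, 56.9 and 79.3 and the class II list at 91.0, 60.3 and 46.3. Complement genes had a median of -0.55 in RPE minus CBPE (percentile 0.34), with none of the 11 measured 2-fold different and percentiles 7.32 after quantile normalization, 4.93 with the floor at the 60th percentile and 6.02 without probe sets that can match several transcripts. It lay at 75.6 in CBPE minus IPE and at 7.38 in RPE minus IPE. C2 was 4.66-fold higher in IPE than in CBPE, and Serping1, a complement inhibitor gene, 2.75-fold higher in IPE than in RPE.

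Among genes above the floor on all 3 arrays that set 1 culture apart from both others, those of IPE repeat the names above, with Aox3, Inmt, Dio2, Heph and Cxadr at least 36.4-fold, 27.3-fold, 21.3-fold, 11.5-fold and 10.7-fold above both and Arhgap20 at 973.2 against 74.9 in CBPE and 55.4 in RPE. Sfrp2, Col14a1, Mfap5, Aspn, Myh2 and Agtr2 were lowest in IPE. CBPE was set apart upward, under the same limit, by Chil1, Wfdc17, Ifi27l2a, Lyz1, Cd53 and Plac8, at least 7.98-fold, 7.84-fold, 7.72-fold, 6.45-fold, 6.24-fold and 6.12-fold above both. Spon1, Ptgds, Folr1, Pax6, Tyrp1 and Cadm1 were lowest in CBPE. RPE was set apart, under the same limit, by Sema3c, a guidance molecule gene, at 6.22-fold, Tmem26 at 4.39-fold, Dlk1 at 3.65-fold, Myl4 at 3.59-fold, Fxyd6 at 3.56-fold and Lpar4 at 3.02-fold. Ndufa4l2 and Egln3, both hypoxia-inducible, were 6.93-fold and 4.59-fold below both in RPE, with Ndrg2, Ak4, Angpt2 and Sfrp4 5.10-fold, 4.21-fold, 4.16-fold and 4.09-fold below. The RPE-enriched and visual cycle list was not higher in RPE: its median was -0.51 in RPE minus CBPE (percentile 0.15) and -0.22 in RPE minus IPE (percentile 4.96), and it lay at percentile 40.2 in CBPE minus IPE. In RPE minus IPE it stood apart at percentiles 0.33 with a pseudocount, 0.76 after quantile normalization and 2.30 with the floor at the 60th percentile. Of its 22 genes on the array, 15 were measured in each comparison with RPE. In RPE, 1 was at least 2-fold higher and 4 lower than in IPE, and none higher and 3 lower than in CBPE. Rlbp1, at 17.3 in RPE, was close to the floor of 16.8, and Ttr, at 9, was under it.

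**Figure D3:**
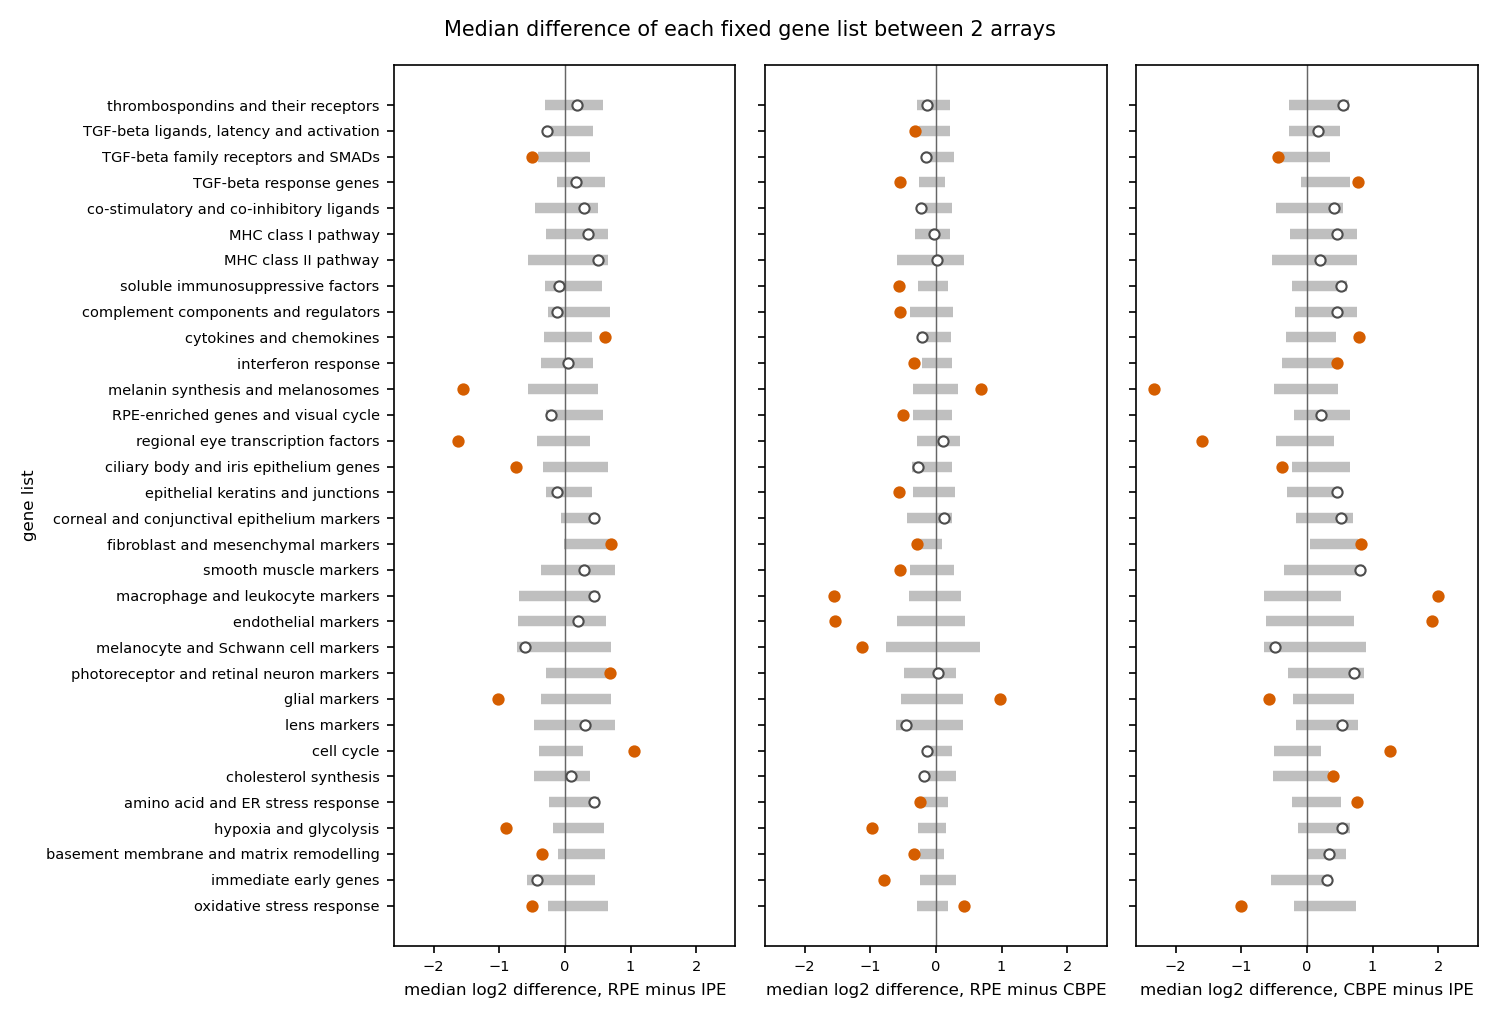
Median log2 difference of each of 32 gene lists in RPE minus IPE, RPE minus CBPE and CBPE minus IPE, with grey bars for the central 95% of 10000 random lists matched on expression. Filled points lie outside the bars, such as melanin synthesis at -1.55, 0.69 and -2.33, and open points lie inside.

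The remaining lists, in the order RPE minus IPE, RPE minus CBPE and CBPE minus IPE, stood as follows. Epithelial keratin and junction genes lay at percentiles 11.4, 0.03 and 94.2, with 2.63 in place of 0.03 with the floor at the 25th percentile. The simple-epithelium keratin gene Krt18 was 2.93-fold higher in CBPE than in IPE, at 422.4 against 144.1, and at 218.6 in RPE. In IPE, CBPE and RPE, Krt8 was at 17.4, 95.3 and 26.2 and Krt19 at 39.9, 25.8 and 2.2. How these RNA signals relate to the cytokeratin-positive shares in the sample descriptions was not tested. Glial markers lay at percentiles 0.02, 100 and 0.13, with Apoe and Glul 13.5-fold and 8.26-fold higher in IPE than in CBPE, but fewer than 5 members were left under 3, 2 and 1 alternatives. Ciliary body and iris epithelium genes lay at percentiles 0.01, 10.3 and 0.64, the last becoming 18.4 with the floor at the 25th percentile, where the median turned from -0.38 to 0.092. Basement membrane and matrix remodelling genes lay at 0.05, 0.04 and 56.5, with 2 of 25 measured at least 2-fold higher, 6 lower and a median of -0.35 in RPE minus IPE. In CBPE minus IPE their median turned from 0.34 to -0.27 after quantile normalization, where it lay at percentile 1.00. Smooth muscle markers lay at percentiles 64.4, 0.34 and 96.1, with 3.43 in place of 0.34 after quantile normalization and 3.93 without probe sets that can match several transcripts. Photoreceptor and retinal neuron markers lay at 98.2, 75.3 and 91.6, with 92.8 in place of 98.2 with a pseudocount and fewer than 5 members left under 2 alternatives. Melanocyte and Schwann cell markers lay at 5.39, 0.11 and 7.60, and the 0.11 in RPE minus CBPE became 9.13 with the floor at the 60th percentile, 2.57 after quantile normalization and 22.2 with the mean of all probe sets, with fewer than 5 members left under 2 others. Lens markers (63.2, 12.3 and 84.7) and corneal and conjunctival markers (95.1, 89.9 and 86.3) did not stand apart as deposited, and the latter lay at 98.1 in CBPE minus IPE after quantile normalization. Interferon response genes lay at 50.8, 0.18 and 98.0, with 94.1 in place of 98.0 after quantile normalization and 3.26 in place of 0.18 without probe sets that can match several transcripts, and 97.3 and 4.68 with the fixed floor of 100. Cholesterol synthesis genes lay at 76.0, 3.78 and 98.7, with 88.9 in place of 98.7 without such probe sets and 96.1 with the mean of all probe sets. The list of thrombospondins and their receptors did not stand apart, at 57.7, 26.0 and 94.0, and TGF-β ligand and activation genes lay at 3.84, 0.69 and 62.7.

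Some lists that did not stand apart as deposited did so under alternatives. In RPE minus IPE these were complement genes under 4 alternatives, amino acid and endoplasmic reticulum stress genes under 3, melanocyte and Schwann cell markers under 2 and leukocyte markers and immediate early genes under 1 each. In RPE minus CBPE they were cytokines under 3, cell cycle genes and photoreceptor markers under 2, and TGF-β receptors and SMADs, ciliary body genes and regional eye transcription factors under 1 each. In CBPE minus IPE they were immediate early genes under 3, epithelial keratins, smooth muscle markers and basement membrane genes under 2, and photoreceptor markers under 1. The others are given beside their lists.

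The split between higher and lower genes depended on the scaling. As deposited, 48.4% of the genes different between CBPE and IPE were higher in CBPE, against 75.4% with equal medians, and for RPE and IPE the shares were 48.5% and 71.9%. For RPE and CBPE they were 46.8% and 34.4%. With equal medians the median of genes above the floor on both arrays moved from -0.03 to 0.31 in CBPE minus IPE and from -0.03 to 0.23 in RPE minus IPE, and with quantile normalization to 0.12 and 0.08, so small differences have a direction only relative to that shift.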

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

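No paired analysis was possible because each culture had 1 array. For the 378 values of named genes, the alternatives gave 2968 recomputed values, of which 2446 stayed within the SD between probe sets of a gene. Of the others, 9 changed the sign of a difference of at least 2-fold and 513 moved without doing so. A further 6 changes of sign, in Cd80, Thbs1 and Tgfb2, concerned differences under 2-fold. Equal medians only shifts each array by a constant, and the shifts were smaller than the SD between probe sets. All 378 values therefore had to stay within that SD under this alternative, and no list percentile could move. Of the 46 list medians that stood apart, 25 did so under every alternative, and in some of the other cases fewer than 5 members were left. A further 19 list medians stood apart under at least 1 alternative and not as deposited. The fixed floor of 100 was chosen after the data were seen, because absent bacterial controls reached 20.2. The causes of the differences below were not tested, except that a lower floor counts more dim genes and a higher floor fewer.

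With the floor at the 25th percentile, 2761 genes were at least 2-fold higher and 1981 lower in RPE than IPE, 1608 and 2001 in RPE than CBPE, and 3396 higher in CBPE than IPE. RPE was then above both others for 685 genes and below for 488, CBPE for 1278 and 679, and IPE below for 1613. With the floor at the 60th percentile, 359 genes were lower in RPE than CBPE, CBPE was above both for 172, and Pde6g was -0.015 (log2) in CBPE minus IPE. With a pseudocount, 792 genes were higher and 1031 lower in RPE than CBPE, RPE was above both for 260 and CBPE for 611, and Cd40 was 0.081 in RPE minus CBPE. After quantile normalization, Thbs1 was -0.19 in RPE minus IPE, -0.45 in RPE minus CBPE and 0.26 in CBPE minus IPE, and in CBPE minus IPE B2m was -0.11, Col3a1 -0.012 and Sparc -0.23. With equal medians, 2028 genes were higher and 791 lower in RPE than IPE, and 2770 and 904 in CBPE than IPE. IPE was then above both for 449 and below for 1424, and CBPE below for 192. With the mean of all probe sets, 268 genes were higher in RPE than CBPE, RPE was below both for 79 and CBPE for 134. Thbs1 was then -0.31 in RPE minus IPE and 0.45 in CBPE minus IPE, and Ccn1 0.060 in RPE minus CBPE. Without probe sets that can match several transcripts, 12 list medians stood apart in RPE minus CBPE against 19, Ccn1 was 1.28 and Mt1 -0.14 in RPE minus CBPE, and Aldoc was 0.21 in RPE minus IPE, the difference between the floors. With the fixed floor of 100, 633 genes were higher and 603 lower in RPE than IPE, 117 and 153 in RPE than CBPE, and 741 and 770 in CBPE than IPE. RPE was above both for 30 and below for 30, IPE for 444 and 451, and CBPE for 87 and 66. The Pearson correlation was then 0.843 for RPE and IPE and 0.823 for CBPE and IPE.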

Other observations

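The second leukocyte and endothelial lists were written before their values were seen, and all other tests and lists here were chosen after results they bear on had been seen. Genes given here as examples from those lists were chosen after their values were seen. Skeletal muscle genes were higher in RPE and CBPE than in IPE, in a list written after Myh2, Mylpf and Myl1 had been seen, which leaves these 3 genes out. Of its 19 measured members, 10 were at least 2-fold higher in RPE than in IPE and none lower, with a median of 1.12, above all 10000 random lists. In CBPE minus IPE 8 of 14 were higher, with a median of 1.19 (percentile 99.99), and in RPE minus CBPE the median was 0.24 (percentile 99.3). The signals of its members were low, unlike Myh2 at 1362.8 in CBPE and 808.8 in RPE: Tnnc1 was at 176.5 in RPE, 70.7 in CBPE and 31.1 in IPE, and Tnnt1 at 113.6 in CBPE and 48.5 in RPE. The Y-linked genes Eif2s3y, Kdm5d and Uty were above the floor in every culture, at 284.2, 137.5 and 100.6 in IPE, 145.5, 80.6 and 22.8 in CBPE and 221, 83.4 and 54.6 in RPE.

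By list median, leukocyte and endothelial markers were higher in CBPE than in both other cultures. Unequal signal distributions between the arrays are argued against, since the smallest of the 4 medians after quantile normalization was 1.75. Scaling to the hybridisation controls, which were 2.58-fold brighter in CBPE than in IPE, was not done. It would lower these medians, so an error of overall scale stays open. The second endothelial list, of which 23 of 28 named genes were above the floor in CBPE and 6 in IPE, had medians of 1.39 against IPE and 1.08 against RPE, both above all random lists, which is what endothelial cells in the CBPE culture could give, with Ecscr at 552.6 and Cd93 at 248.1. The second leukocyte list, with 20 of 34 above the floor in CBPE and 6 in IPE, had medians of 1.05 and 0.84, the latter under the 1 set beforehand, so leukocytes stay open, with Arhgdib at 472.9 and Lcp1 at 130.8. The rule for naming genes also picks Cd93 and Lcp1. Without Cd93 the endothelial medians were 1.35 against IPE and 1.07 against RPE, and without Lcp1 the leukocyte medians were 1.04 and 0.78. The sample descriptions give above 95% cytokeratin-positive cells for CBPE, which limits leukocytes and endothelial cells there but does not exclude them. Expression of the leukocyte and endothelial genes by the ciliary epithelium itself was not tested, and tissue and culture are confounded.

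Melanin genes and eye transcription factors were higher in IPE than in both other cultures, as were glial markers such as Apoe, which were not weighed as an explanation. Unequal signal distributions are argued against by the smallest median after quantile normalization, 1.28. Scaling to the hybridisation controls was not done here either. It would widen these differences, since the controls were dimmest in IPE. What is known of growth medium rests on the protocols: IPE and CBPE shared medium and serum, while for RPE medium is confounded with tissue. Melanocytes in IPE remain possible: a melanocyte list, 5 of its genes also in a list above, had medians toward IPE of 0.48 against CBPE and 0.63 against RPE (percentiles 99.55 and 99.37), the smaller between the bounds set, with Tfap2b at 1096 but Sox10 at 25.7 and Kit at the floor. The sample descriptions give above 99% cytokeratin-positive cells for IPE and above 95% for CBPE and RPE, which limits such cells in IPE but does not exclude them. An equal loss of pigment epithelial cells in CBPE was tested by the SD of the melanin gene differences, 1.21, and the test was dropped because other causes spread these values too, so a lower share of such cells and a difference between the tissues stay open.

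The 2 Thbs1 probe sets differed by 1.30 in their log2 difference between CBPE and IPE, more than in 93.0% of genes with 2 such probe sets. Compression of bright signals on the IPE array could not be tested by quantile normalization, after which they stayed 1.16 apart. At 2992 and 3146 in IPE, any rescaling of that array moves both probe sets nearly alike, so this distance was bound to change little. A 3′ bias of the RNA cannot be told apart, because the Actb 3′ to 5′ ratio was higher by 0.59 (log2) in CBPE than in IPE but the positions of the probe sets were not used here. No biological explanation, such as transcripts with different 3′ ends, was tested.

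One hypothesis was that melanin genes may be higher in IPE as part of a wider melanosome programme. A melanosome biogenesis list, of which the values of Slc7a11 and Slc3a2 had been seen, had medians toward IPE of 0.50 against CBPE (percentile 98.8) and 0.31 against RPE (percentile 92.5). The latter lay inside the central 95% of random lists, so the hypothesis stays open.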
